A study of Arabidopsis with 12 samples.

How the data were processed

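Total RNA of whole seedlings was measured on 12 Affymetrix Arabidopsis arrays, with biotin-labelled cRNA made from 100 ng of RNA per the labels' protocols. The deposited table holds 1 value per probe set and array for 38408 probe sets. Its values run from about 1.13 to 13.2 with none missing and were taken as log2 levels, since the deposited table does not name its scale. The values come from Transcriptome Analysis Console 4.0.1, per the submitters' processing notes. The background correction, normalization and summarization methods are not given in the sources used here, so their effect on the measurements is unknown. All 12 value columns belonged to labelled samples and 0 were left unmapped. The scanner files were not used here.

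The probe annotation lists 17481 of the 38408 probe sets, 16722 with 1 gene and 759 with several, and 20927 probe sets (54.5%) are unnamed here. Probe sets of several genes were left out. Names were updated through the RefSeq gene table of assembly TAIR10.1, which matched 16411 of the genes, and 139 genes were named by the array annotation alone. No coordinates are printed, because the sources used here name no build. Each gene was represented by its brightest probe set, by the mean over all 12 arrays, which mattered for 146 genes with more than 1. This left 16550 genes. They include 16406 of the 27550 protein-coding genes of the reference but 1761 of the 10481 that have a symbol other than the locus, so many well-known genes, TOR among them, were not analysed here.

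Samples were grouped by the genotype and treatment in the labels into Col-0 control, Col-0 water deficit, tori 35-7 control and tori 35-7 water deficit, with 3 arrays each. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples only, which may be technical. No 2 arrays held identical values. A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates. It gave 5 comparisons: water deficit against control in each genotype, their difference (the interaction), and tori 35-7 against Col-0 on each medium. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 16550 genes, two-sided, with a threshold of 0.05. All genes counted as past the threshold in a comparison of 2 groups had groups that did not overlap, which chance gives for 10% of genes with 3 arrays against 3.

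The text names genes by a rule set before the data were examined. It takes, for the water-deficit comparisons and the interaction, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap (for the interaction without that condition). For the comparisons of genotypes it takes 6 in each direction. It adds up to 4 members of each fixed gene list with the smallest unadjusted p. There were 32 such lists with 437 members, of which 79 were measured. Of the lists, 10 had at least 3 measured members and were tested, 10 had 1 or 2, and 12 had none, among them aquaporins, cytosolic ribosomal proteins, abscisic acid synthesis and osmolyte synthesis, which were not analysed here. The 50 tests used camera with its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 50. With an estimated correlation 0 of the 50 passed, so none of the calls with the preset correlation held. Fry, which tests whether the genes of a list move one way on balance, gave 8 adjusted p-values under 0.05. In 4 of the 50 tests, none of them past the threshold, the median, the mean and the test differed in sign.

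The steps were tested on simulated data with the means and spreads of the 16550 genes and 200 changed genes per comparison. For water deficit in Col-0 81% of 2-fold and 98% of 4-fold changes were recovered, with 7 false calls, and for tori 35-7 78% and 99%, with 5. For the interaction 48% and 98% were recovered, with 11 false calls. For the genotypes on control medium 81% and 100% were recovered with 9 false calls, and under water deficit 82% and 100% with 6. A set of 12 shifted genes was found and 0 of 50 unshifted sets were called, and a true ratio of responses of 0.5 was recovered as 0.494. The simulated genes varied independently of each other, with the same spread on every array, and all changed genes had that ratio. These tests therefore cannot show whether the preset correlation suits the measured genes, or how a compressed array or unequal ratios would act.

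The alternatives were quantile normalization between arrays, centring each array on its median, leaving out genes at or below the 25th percentile of mean level, eBayes with a trend and robust priors, array weights, a fit on the 6 arrays compared, replicate number as a block, the mean of a gene's probe sets, thresholds with a 2-fold minimum, and each array left out in turn. All probe sets, named or not, a fit without 2 arrays that stood apart and overlaps of lists from separate fits on 6 arrays were added after the data were seen.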

Results

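Gene expression was measured on Affymetrix Arabidopsis arrays in whole seedlings of 2 genotypes on 2 media. Col-0 is the standard laboratory accession. The other genotype, tori 35-7, is named without further description in the labels, and the series title refers to TOR, the Target of Rapamycin kinase that couples nutrient and energy supply to growth. After 5 days of growth at 22 °C, seedlings spent 72 h on control medium with 0.8% agar or on water-deficit medium with 2% agar, and they were sampled at 8 days of age. Each of the 4 groups had 3 arrays, so the number of arrays limits the precision. The median log2 level of all probe sets lay between 3.06 and 3.19 on every array. Values below are log2 probe set levels with SD over n = 3 arrays, or log2 differences with the standard error of the model fitted to all 12 arrays.

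TOR itself (AT1G50030) was not analysed here, because the probe annotation used here lists no probe set for it. Its level in either genotype is therefore not known from these values. Of the 15 members of the fixed list of TOR complex and TOR signalling genes, 3 were measured, and none passed the test in any of the 5 comparisons. The largest value among them was that of AT5G63190, 0.43 ± 0.14 higher in tori 35-7 than in Col-0 under water deficit (adjusted p = 0.2, and 0.0298 adjusted over the list alone).

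The first comparison asked which genes respond to water deficit in Col-0. Genes of the iron-deficiency response were among the largest rises. The fixed list of iron-deficiency genes, to which BHLH101 belongs, had fewer than 3 measured members and was not tested. BHLH101, a transcription factor induced by iron deficiency, rose from 3.02 ± 0.16 to 6.06 ± 0.34, which is 8.26-fold (difference 3.05 ± 0.17, adjusted p = 5.42e-07). The genes of IRONMAN peptides, which promote iron uptake, rose as well, AT1G47395 by 2.16 ± 0.16 and AT1G47400 by 1.84 ± 0.17. Further genes known to be induced by iron deficiency also rose, namely AT2G14247 (2.81 ± 0.24), AT5G05250 (2.09 ± 0.14) and AT1G13609, which encodes a defensin-like peptide (2.97 ± 0.48). The other large rises were those of the stress protein gene COR15A (from 5.11 ± 0.75 to 7.20 ± 0.91), of the glutathione transferase gene GSTU25 (1.91 ± 0.18), and of AT4G32950 (1.84 ± 0.18) and AT1G60590 (1.82 ± 0.19). Among the 10 largest falls were 5 genes of CC-type glutaredoxins, small redox proteins specific to land plants. AT4G15680 fell by 1.84 ± 0.21, AT4G15670 by 1.82 ± 0.22, AT4G15700 by 1.47 ± 0.21, AT4G15660 by 1.40 ± 0.28 and AT5G18600 by 1.37 ± 0.20. The AT4G15660 to AT4G15700 genes are close relatives, so their probe sets are not certain to tell them apart. The remaining falls were those of AT1G52060 (-1.85 ± 0.26), AT5G57760 (-1.74 ± 0.19), AT5G47610 (-1.66 ± 0.29), AT1G27020 (-1.52 ± 0.24) and AT5G08760 (-1.43 ± 0.19).

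In all, 203 of 16550 genes passed adjusted p 0.05 in Col-0, 111 higher and 92 lower under water deficit, and 74 of them differed at least 2-fold. The split depended on the setting: it was 84 higher and 101 lower with each array centred on its median, 244 and 87 without Col-0 water deficit replicate 1, 104 and 178 without replicate 2, 119 and 149 without replicate 3, and 319 and 142 without the 2 arrays with the narrowest spread. Of the 7 measured members of the list of abscisic acid and dehydration response genes, 3 rose, none fell and 4 did not pass. These were COR15A, COR15B (1.68 ± 0.17), which like COR15A protects chloroplast membranes during dehydration, and KIN2 (1.70 ± 0.17), a cold- and abscisic acid-induced gene. COR15A with COR15B, and KIN2 with KIN1, are close relatives. The list as a whole shifted upwards (camera adjusted p = 1.51e-07), with an adjusted p = 0.0587 with an estimated correlation. Adjusted over the list alone, 3 members passed. Of 4 measured genes of anthocyanin and flavonol synthesis, DFR, the dihydroflavonol reductase, rose (1.07 ± 0.20, adjusted p = 0.0163) and 3 did not pass. Of 12 expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, EXPA8 rose (adjusted p = 0.0202) and 3 passed when adjusted over the list alone. Of 5 nuclear photosynthesis genes, LHCB4.2, which encodes an antenna protein of photosystem II, rose (0.71 ± 0.15). Adjusted over the list alone 3 of the 5 passed, and these did not all change in the same direction. The median change of those 5 was -0.05 and their mean 0.15, and neither list passed the camera test. Of 15 autophagy genes and of 8 nucleolar ribosome assembly factors none passed. The 3 stomatal lineage markers had a median change of 0.47 and the 2 root hair markers one of 0.08, with no member past the threshold. Col-0 water deficit replicate 1 stood apart from the other 11 arrays, with a median correlation of 0.950 to them and a narrower spread of values (interquartile range 2.56, against 2.68 to 3.08 elsewhere). Without it the count was 331, without Col-0 control replicates 1, 2 and 3 it was 72, 84 and 88, and it was 39 when only the 6 Col-0 arrays were fitted. COR15A, AT4G15660 and AT5G47610 were no longer called without Col-0 control replicate 3, COR15A and AT4G15660 also without control replicate 1 or water deficit replicate 2, and COR15A without water deficit replicate 3 and AT4G15660 without control replicate 2. In the settings other than leaving out 1 array, 14 of the 20 genes named were called in every one. AT1G13609 (adjusted p up to 0.106), AT1G52060 (up to 0.0639) and AT1G27020 (up to 0.111) were called in 8 of 9 of these, as were COR15A, AT4G15660 and AT5G47610.

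**Figure D1:**
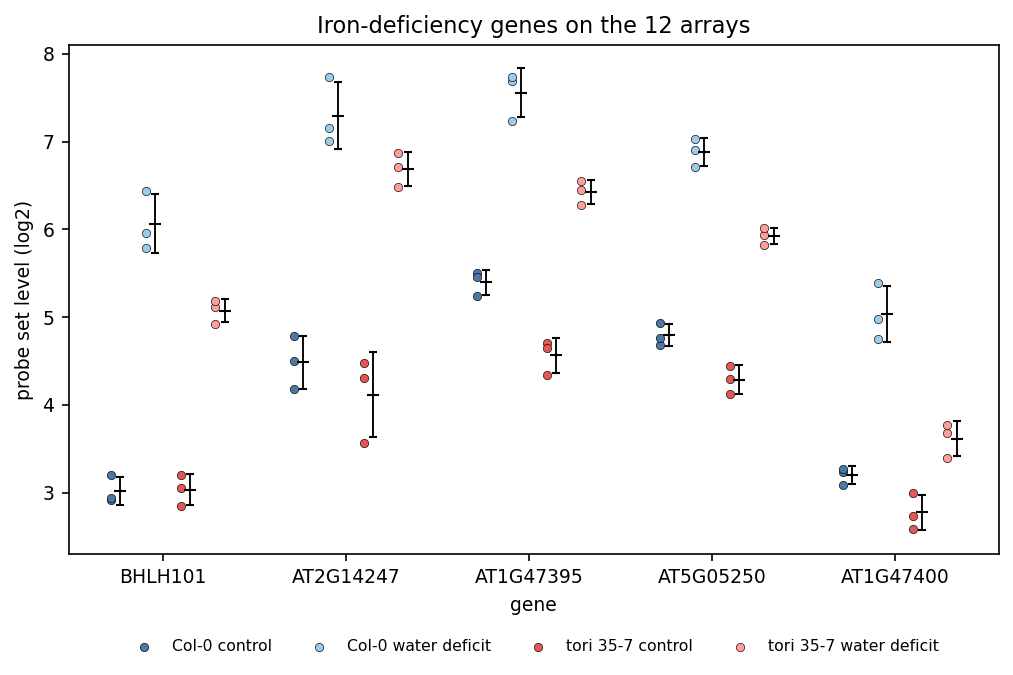
Log2 level of 5 iron-deficiency genes (x axis) on each of the 12 arrays (y axis, log2), with colours for the 4 groups and bars for the mean ± SD of 3 arrays. The 5 genes are higher on water-deficit than on control medium in both genotypes, with BHLH101 at 6.06 in Col-0 and 5.07 in tori 35-7 under water deficit against 3.02 and 3.03 on control medium.

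The second comparison asked the same of tori 35-7. COR15A had the largest rise, from 4.96 ± 0.55 to 7.74 ± 0.29 or 6.87-fold (difference 2.78 ± 0.42, adjusted p = 0.00437). Iron-deficiency genes rose here too, AT2G14247 by 2.57 ± 0.24, BHLH101 by 2.04 ± 0.17, AT1G47395 by 1.86 ± 0.16 and AT5G05250 by 1.64 ± 0.14. GSTU25 rose by 1.61 ± 0.18, and UGT85A5, a glucosyltransferase gene, by 1.57 ± 0.15. AT2G28780 (1.62 ± 0.23), the extensin-like gene AT2G15880 (1.61 ± 0.29) and AT1G05340 (1.53 ± 0.16) completed the 10 largest rises. The largest fall was that of AT5G42530, from 6.81 ± 0.28 to 3.82 ± 0.71. It was followed by AT1G65490 (-2.09 ± 0.17) and by a pair of genes known to be induced by low oxygen. Of these, AT3G10040, a trihelix transcription factor known as an attenuator of the low-oxygen response, fell by 1.91 ± 0.22, and AT3G27220, which encodes a kelch-repeat protein, fell by 1.81 ± 0.26. The other falls were those of AT2G25510 (-1.74 ± 0.23), AT4G22470 (-1.68 ± 0.20), AT5G08760 (-1.67 ± 0.19), AT1G68238 (-1.57 ± 0.33), AT5G33355 (-1.55 ± 0.25) and AT1G60110 (-1.40 ± 0.29).

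In tori 35-7, 192 genes passed adjusted p 0.05, 136 higher and 56 lower under water deficit, 63 of them at least 2-fold. The numbers were 407 higher and 261 lower with array weights, and 185 and 127 without the 2 arrays with the narrowest spread. The same 3 of 7 abscisic acid and dehydration response genes rose as in Col-0, COR15A, COR15B (1.07 ± 0.17) and KIN2 (1.01 ± 0.17), and 4 did not pass (camera adjusted p = 1.06e-05, and adjusted p = 0.0759 with an estimated correlation). Adjusted over the list alone, 4 passed, the further gene being the dehydrin LTI30 (0.42 ± 0.14). Of 5 nuclear photosynthesis genes LHCB4.2 rose (1.08 ± 0.15), and LHCB4.1 (0.52 ± 0.14) and PSAE-1 (0.52 ± 0.16) passed only when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.184 with an estimated correlation). Of 6 auxin response genes IAA29, an auxin-induced repressor, rose (1.46 ± 0.20), and 3 passed when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.277 with an estimated correlation). This list call was lost without tori 35-7 control replicate 3 (0.0712) and without the 2 arrays with the narrowest spread (0.0555). None of 15 autophagy genes passed singly or adjusted over the list alone. Their median was 0.22 higher under water deficit, with ATG8E at 0.38 ± 0.12 and ATG8H at 0.41 ± 0.14 (camera adjusted p = 0.00823, and adjusted p = 0.267 with an estimated correlation). Of 12 expansin and xyloglucan endotransglucosylase genes EXPA8 (1.52 ± 0.21) and EXPA4 (0.64 ± 0.14) rose and 10 did not pass, with 4 past the threshold adjusted over the list alone and no shift of the list (camera adjusted p = 0.689). Among 3 stomatal lineage markers FMA, a guard cell fate regulator, rose (0.85 ± 0.18, adjusted p = 0.0353), and the median of the 2 root hair markers was 0.11 higher. The tori 35-7 control arrays included replicate 1, the array with the second narrowest spread (interquartile range 2.68). The count of genes was 98, 100 and 80 without tori 35-7 control replicates 1, 2 and 3, it was 94, 71 and 70 without water-deficit replicates 1, 2 and 3 of this genotype, and it was 387 without Col-0 water deficit replicate 1. AT2G15880, AT1G68238, AT5G33355 and AT1G60110 were no longer called without tori 35-7 water deficit replicate 3, and all of these but AT5G33355 were lost without other single arrays as well.

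The third comparison was whether the response differs between the genotypes, tested as the interaction of genotype and medium. One gene passed, AT3G10040, with an interaction of -2.36 ± 0.32 (adjusted p = 0.0436). Its level was 2.49 ± 0.26 and 2.94 ± 0.04 in Col-0 on control and water-deficit medium, against 5.23 ± 0.55 and 3.31 ± 0.21 in tori 35-7. AT3G27220 had the same pattern of levels, 3.82 ± 0.19 and 3.84 ± 0.16 in Col-0 against 6.05 ± 0.69 and 4.24 ± 0.24 in tori 35-7, without passing (-1.83 ± 0.37, adjusted p = 0.326). IAA29 was at 2.47 ± 0.19 and 2.53 ± 0.12 in Col-0 and at 3.04 ± 0.20 and 4.50 ± 0.48 in tori 35-7, an interaction of 1.41 ± 0.29 (adjusted p = 0.326, and 0.00129 adjusted over its list alone). BHLH101 had an interaction of -1.01 ± 0.24 (adjusted p = 0.707) and DFR one of -0.90 ± 0.28 (adjusted p = 0.763, and 0.0232 adjusted over its list alone). None of the fixed gene lists passed for the interaction. At an unadjusted p under 0.05 there were 1006 genes, against 827.5 from chance alone. The call of AT3G10040 held without tori 35-7 control replicate 1, where AT3G27220 passed too, and was lost without each of the other 11 arrays in turn and when each array was centred on its median (adjusted p = 0.0575).

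**Figure D2:**
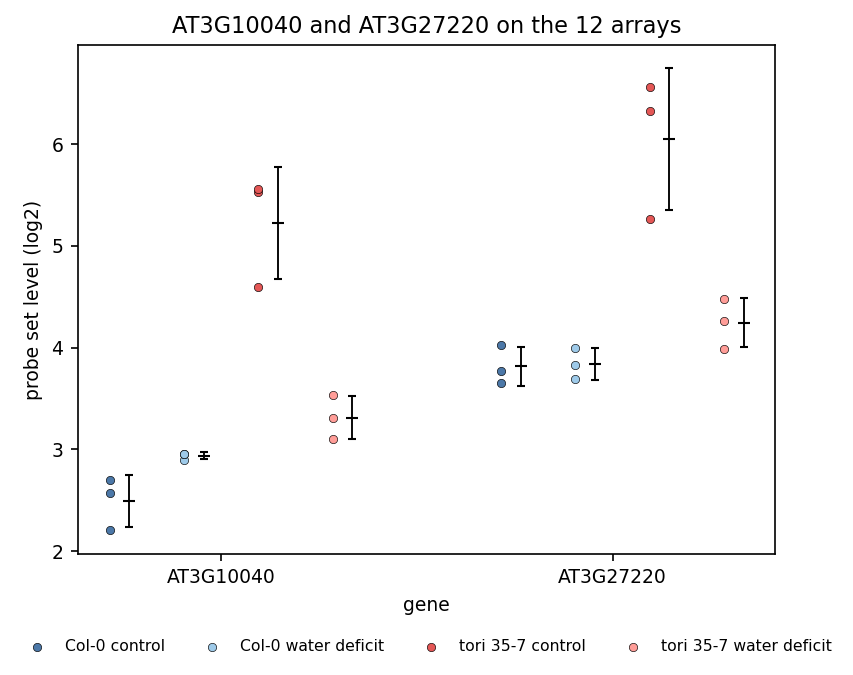
Log2 level of AT3G10040 and AT3G27220 (x axis) on each of the 12 arrays (y axis, log2), with colours for the 4 groups and bars for the mean ± SD of 3 arrays. Both genes are highest in tori 35-7 on control medium, at 5.23 and 6.05, and lie between 2.49 and 4.24 in the other 3 groups.

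The responses of the genotypes were then set against each other over genes. Of the genes that rose, 49 were shared by Col-0 and tori 35-7, where 0.912 would be shared by independent lists, and of those that fell 25 were shared, against 0.311. No gene was called in opposite directions. These 2 responses share no arrays, but every call used the spread over all 12 arrays, so 0.912 and 0.311 are not exact values for lists without a common response. With each genotype fitted on its own 6 arrays, a test chosen after the first counts were seen, 18 of the 22 genes that rose in Col-0 were shared, against 0.259, and 9 of the 17 that fell, against 0.0924. Over the 321 genes called in either genotype, 92.2% changed in the same direction and the correlation of the log2 changes across genes was 0.785, where genes are not independent replicates and were chosen on these arrays. Over all 16550 genes the correlation was 0.36. To compare the size of the responses without the bias of choosing and measuring on the same arrays, genes were chosen with 1 array of each group of 1 genotype left out and measured on the arrays left out, in 9 choices. Genes chosen on Col-0 had a median change of 0.808 ± 0.219 in the left-out Col-0 arrays and 0.692 ± 0.0810 in tori 35-7 (mean ± SD over choices), a ratio of tori 35-7 to Col-0 of 0.857 with single choices between 0.712 and 1.30. Genes chosen on tori 35-7 had a median change of 1.23 ± 0.125 in tori 35-7 and 0.878 ± 0.0754 in Col-0, a ratio of Col-0 to tori 35-7 of 0.715, or of tori 35-7 to Col-0 of 1.40. The first ratio depended on the array left out: with Col-0 water deficit replicate 1 as the measured array it was 0.927, 1.30 and 1.29, and with replicates 2 and 3 it lay between 0.712 and 0.856. A smaller response in tori 35-7 is thus not shown, since tori 35-7 had the larger change in 2 of these 9 choices and at the genes chosen on tori 35-7.

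**Figure D3:**
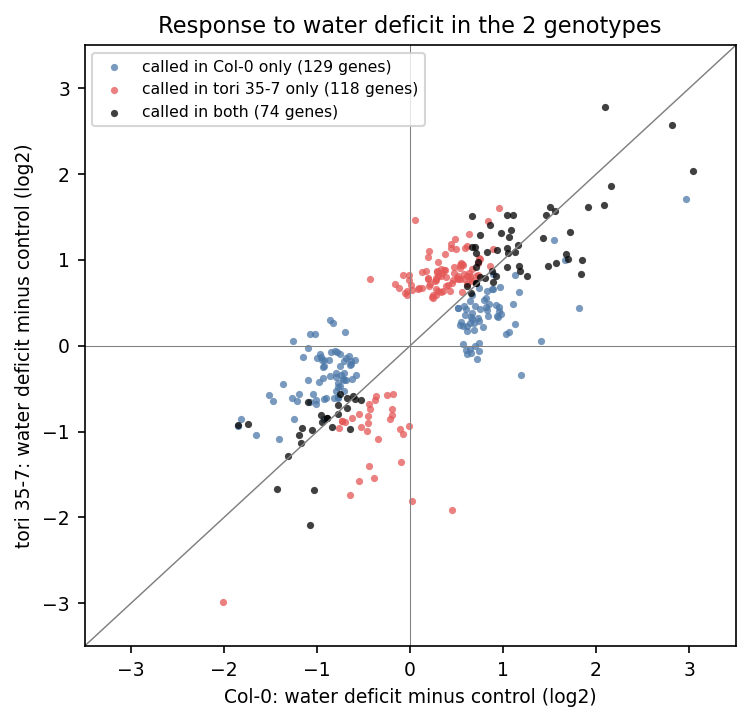
Log2 change under water deficit in Col-0 (x axis) and in tori 35-7 (y axis) for genes past adjusted p 0.05 in either genotype, 1 point per gene, with the line of equal change. Black points are the 74 genes called in both genotypes, blue points the 129 called in Col-0 alone and red points the 118 called in tori 35-7 alone, and 92.2% of all points have the same sign on both axes.

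The fourth comparison was between the genotypes on control medium. AT3G10040 was 6.66-fold higher in tori 35-7 than in Col-0 (difference 2.74 ± 0.22, adjusted p = 9.34e-05) and AT3G27220 was 4.70-fold higher (2.23 ± 0.26, adjusted p = 0.00204). These differences and the falls of both genes under water deficit rest on the same 3 tori 35-7 control arrays. QQS, an orphan gene that affects the allocation of carbon to starch and protein, was higher by 2.05 ± 0.20, from 5.06 ± 0.27 in Col-0 to 7.11 ± 0.19. AT1G02610 (1.83 ± 0.37), AT3G01345 (1.63 ± 0.24) and AT2G01023 (1.52 ± 0.22) were also higher. Lower in tori 35-7 were AT2G01130 (-1.70 ± 0.17), the organelle RNA splicing gene OTP70 (-1.44 ± 0.17), AT3G28270 (-1.34 ± 0.24), AT4G11410 (-1.25 ± 0.20), the mitochondrial D-lactate dehydrogenase gene AT5G06580 (-1.20 ± 0.15) and AT4G24630 (-1.17 ± 0.19). In all 94 genes passed, 45 higher and 49 lower in tori 35-7, and 37 differed at least 2-fold. The split was 82 higher and 151 lower without Col-0 water deficit replicate 1, 174 and 247 with array weights, 19 and 7 without Col-0 control replicate 3, and 20 and 8 without tori 35-7 control replicate 1, so its direction depended on the setting. Of 12 expansin and xyloglucan endotransglucosylase genes none passed singly and 4 passed adjusted over the list alone, EXPA8 (0.79 ± 0.21), EXPA15 (0.62 ± 0.16), EXPA4 (0.50 ± 0.14) and XTH33 (0.49 ± 0.15). The list shifted upwards (camera adjusted p = 0.0181, and adjusted p = 0.184 with an estimated correlation), a call lost without tori 35-7 control replicate 3 (0.082). The stomatal marker FMA was 0.78 ± 0.18 lower in tori 35-7 without passing (adjusted p = 0.077), the median of the 3 stomatal markers was -0.19 and that of the 2 root hair markers -0.13. Among 3 reference genes the TIP41-like gene AT4G34270, often used as a stable control, had a difference of -0.89 ± 0.20 (adjusted p = 0.0656, and 0.00155 adjusted over the list alone). The count of genes fell to between 11 and 28 without single arrays of either control group, the lowest without Col-0 control replicate 2, and was 233 without Col-0 water deficit replicate 1. Of the 12 genes named, AT3G10040, AT3G27220, QQS, AT2G01130, OTP70 and AT5G06580 were called without each of the 12 arrays in turn. The other 6 were not, with AT1G02610 called without 3 of the 12, AT3G28270 and AT4G11410 without 6, AT3G01345 and AT4G24630 without 8 and AT2G01023 without 11.

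The fifth comparison was between the genotypes under water deficit. QQS was again higher in tori 35-7, at 6.94 ± 0.05 against 4.74 ± 0.45 in Col-0 or 4.59-fold (adjusted p = 2.02e-04). IAA29 was higher by 1.97 ± 0.20, AT1G22570 by 1.63 ± 0.14, the peroxidase gene AT5G39580 by 1.54 ± 0.30 and the beta-glucosidase gene BGLU45 by 1.53 ± 0.18. AT1G02610 was higher by 1.85 ± 0.37. Of the 5 plotted iron-deficiency genes, 4 were lower in tori 35-7 than in Col-0 under water deficit, AT1G47400 by a log2 difference of -1.42 ± 0.17, AT1G47395 of -1.13 ± 0.16, BHLH101 of -0.99 ± 0.17 (adjusted p = 0.0198) and AT5G05250 of -0.96 ± 0.14, and AT2G14247 did not pass (-0.61 ± 0.24, adjusted p = 0.295). Of these AT1G47395 passed as lower on control medium as well (-0.83 ± 0.16). AT5G05250 and AT1G47400 did not pass there, but their mean levels were also lower in tori 35-7. The means were 4.29 against 4.79 in Col-0 for AT5G05250, and 2.773 against 3.199 for AT1G47400. BHLH101 was not lower there, at 3.03 against 3.02. Lower mean levels of AT1G47395, AT5G05250 and AT1G47400 were thus not confined to water deficit. All 5 plotted genes were picked from the largest rises in Col-0, on the same 3 Col-0 water-deficit arrays. That choice favours lower values in tori 35-7 under water deficit. AT5G24155 (-1.69 ± 0.23), AT2G31440 (-1.60 ± 0.25), AT1G60590 (-1.42 ± 0.19), AT4G31310 (-1.32 ± 0.20) and AT5G63000 (-1.21 ± 0.19) made up the rest of the largest negative differences. Of 6 auxin response genes IAA29 and GH3.3, an auxin-conjugating enzyme gene (adjusted p = 0.0363), were higher, 4 did not pass, and 3 passed when adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.267 with an estimated correlation). The auxin call was lost without Col-0 water deficit replicate 3 (0.0706). Of 5 photosynthesis genes LHCB4.2 was higher (0.88 ± 0.15), 4 did not pass, and 3 passed when adjusted over the list alone (camera adjusted p = 0.0325, and adjusted p = 0.215 with an estimated correlation). That list call was lost under 5 of 21 alternatives, with adjusted p up to 0.143. EXPA8 (1.21 ± 0.21) and EXPA4 (0.70 ± 0.14) were the 2 expansins that passed, of 12 measured genes of that list, and 4 passed when adjusted over the list alone. AKINBETA1, which encodes a subunit of the energy-sensing kinase SnRK1 and was the 1 measured member of the sugar-starvation list, was higher by 1.15 ± 0.20 (adjusted p = 0.0203). The median of the 3 stomatal markers was -0.41 and that of the 2 root hair markers -0.09.

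Under water deficit 136 genes passed between the genotypes, 82 higher and 54 lower in tori 35-7, and 36 differed at least 2-fold. With each array centred on its median the split was 119 higher and 45 lower. It turned to 168 higher and 276 lower without the 2 arrays with the narrowest spread, to 86 and 148 without Col-0 water deficit replicate 1 alone, and to 109 and 122 with array weights, so its direction depended on the setting. With quantile normalization 60.4% of the genes called were higher, and the fit on the 6 arrays compared gave 5 higher and 3 lower. Between the 2 media, 10 genes were higher in tori 35-7 on both, where independent lists would share 0.223, and 9 were lower on both, against 0.16. These calls too used the spread over all 12 arrays, and with each medium fitted on its own 6 arrays 2 genes were shared of the 5 that were higher under water deficit and 0 of the 3 that were lower. The shared genes included AT4G24450, a gene of the glucan water dikinase family that phosphorylates starch (0.71 ± 0.14 on control medium and 0.75 ± 0.14 under water deficit), and the asparaginase gene ASPGA1 (-0.97 ± 0.14 and -0.94 ± 0.14), both chosen after their values were seen. The count under water deficit was 37, 23 and 21 without tori 35-7 water deficit replicates 1, 2 and 3, and 234, 205 and 241 without Col-0 water deficit replicates 1, 2 and 3. Fitted on the 6 arrays compared it was 8. Of the 12 genes named, AT1G02610, AT5G39580, AT2G31440, AT4G31310 and AT5G63000 were no longer called without tori 35-7 water deficit replicate 3. The last 2 were called without each of the other 11 arrays, AT2G31440 was called without 10 of the 12, AT5G39580 without 8 and AT1G02610 without 5. In the settings other than leaving out 1 array, 6 of the 12 were called in every one. The rest, AT1G47400 (adjusted p up to 0.0536) besides those 5, were called in 8 of 9.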

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

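The tests of compressed signal and of the agar were chosen only after their results were seen, as was the fit without 2 arrays.

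AT3G10040 was picked out because its response to water deficit differed between the genotypes (interaction -2.36). Of 100 splits of the media within each genotype, drawn from 200, 6 gave at least 1 gene, the real one included, so chance cannot be excluded for a count of 1. The other 99 splits held 5 of these. The highest of them, with 612 genes, exchanged all medium labels of tori 35-7 and so measured the response shared by both genotypes rather than chance, and the next gave 21. Other splits can carry a part of that shared response too, so the count of 6 does not measure chance alone.

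AT3G10040 and AT3G27220 were both highest in tori 35-7 on control medium. The 2 arrays with the narrowest spread do not account for this, since without them the smaller of the 2 differences from Col-0 was 2.63. A hypothesis is a wider low-oxygen response in tori 35-7. Over 25 other genes known to be induced by low oxygen, not seen before the test, the median difference on control medium was 0.17 (21 of 25 above 0, camera adjusted p = 2.13e-06, and adjusted p = 0.0139 with an estimated correlation), and the call was kept without each of the 12 arrays in turn. Under water deficit it was 0.07 (17 of 25 above 0, camera adjusted p = 0.0341, and adjusted p = 0.157 with an estimated correlation), and that call was lost without Col-0 water deficit replicate 2 (0.0728) or 3 (0.132) and without tori 35-7 water deficit replicate 1 (0.0883). Their median interaction was -0.12 (camera adjusted p = 0.0415, and adjusted p = 0.159 with an estimated correlation). With each of the 12 arrays left out in turn, its unadjusted camera p was under 0.05 in 9 cases. It was 0.248 without tori 35-7 control replicate 2, so it stays open whether the shift is confined to control medium. The adjusted p-values of the 25 genes cover fewer tests than those of the fixed lists, so the 2 cannot be compared. With an estimated correlation the unadjusted camera p on control medium was 0.00278. For the abscisic acid and dehydration list in Col-0 it was smaller, 0.00117, yet its adjusted p was 0.0587. The shift is small beside the 2 genes: 1 of the 25 passed singly on control medium, AT4G27450 (1.25 ± 0.21, and 1.02 ± 0.21 under water deficit), and PDC2, a fermentation gene, was at -0.14 ± 0.16, so what sets the 2 genes apart stays open. In tori 35-7, where the 2 genes fell under water deficit, the 25 had a median change of -0.06 (camera adjusted p = 0.562), with 2 called higher and 2 lower. The 25 include AT2G15880, which rose there by 1.61 ± 0.29. On control medium AT2G15880 was at 5.08 ± 0.27 in tori 35-7 and 4.35 ± 0.26 in Col-0.

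Col-0 water deficit replicate 1 stood apart from the other arrays. Its deviation from the other 2 arrays of its group fell with their level with a slope of -0.128, below the range of the other 11 arrays (-0.0732 to 0.0646), which is consistent with compressed signal on that array. Tori 35-7 control replicate 1 had the next lowest slope. A control sample under a water-deficit label is argued against. Of the 331 genes called without this array, 82.5% differed on it in the called direction. Their median aligned change was 0.469 on it, against 0.851 and 0.797 on replicates 2 and 3. Replicates 2 and 3 helped to choose these genes, so their medians are overstated by the choice. The same Col-0 control mean served to choose and to measure, which favours the called direction on this array too. No biological explanation was tested for it.

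Probe sets without a listed gene gave signals outside the comparisons above. Probe set 13545557 was 5.67 higher in tori 35-7 than in Col-0 on control medium (mean level 8.31 against 2.64) and 5.43 higher under water deficit, and another was 4.80 higher on control medium and 4.48 under water deficit. In Col-0, probe set 13419754 was 4.55 higher under water deficit and another was 2.37 higher, and in tori 35-7 they were 2.96 and 2.29 higher.

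The 6 arrays of each comparison of 2 groups make only 10 splits, too few for a share under 0.05. In each comparison 1 of the 10, the real one, reached the real count, and the highest of the others gave 0 genes. The other splits mix arrays of both real groups, so a real difference widens their spread and lowers their counts. Their 0 genes are therefore not a measure of chance. The real counts were 203 for water deficit in Col-0, 192 in tori 35-7, 94 between genotypes on control medium and 136 under water deficit.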

How the results depend on the processing

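The fit without 2 arrays (Col-0 water deficit replicate 1 and tori 35-7 control replicate 1) and that on all probe sets, and the overlap from separate fits, were chosen after the data were seen, and the cause was not tested for any of the shifts below. The counts are given in the order water deficit in Col-0, water deficit in tori 35-7, interaction, genotypes on control medium and genotypes under water deficit, against 203, 192, 1, 94 and 136. With array weights they were 311, 668, 2, 421 and 231, and without the 2 arrays 461, 312, 2, 153 and 444, of which 194, 177, 1, 81 and 132 were genes already called. At adjusted p 0.05 and at least 2-fold they were 74, 63, 1, 37 and 36, and at unadjusted p 0.05 and at least 2-fold 84, 75, 47, 48 and 54. Over all probe sets they were 329, 213, 0, 42 and 113, with more tests to adjust for. Quantile normalization gave 325 for water deficit in Col-0 and 265 between genotypes under water deficit, and the fit on the 6 arrays compared gave 39 and 8 for these. Centring each array gave 0 for the interaction, where AT3G10040 had an adjusted p of 0.0575. With each array left out the counts ran from 72 to 331, 70 to 387, 0 to 2, 11 to 233 and 21 to 241. Without Col-0 water deficit replicate 1 they were 331, 387, 0, 233 and 234. The genes shared by both responses numbered 168 with array weights, 143 without the 2 arrays, 28 at 2-fold in both, 27 with each list from a fit on its own 6 arrays, and 37 to 145 with each array left out, against 74. The gene list tests past the threshold numbered 0 with an estimated correlation and 6 to 10 with each array left out, against 8. The ratio of response sizes of 0.857 (tori 35-7 to Col-0) was 0.655 for genes chosen and measured on the same arrays, within the SD over choices of 0.230. For genes chosen on tori 35-7 it was 1.40, outside that SD, so the choice of genes sets which genotype has the larger change. The choices reuse the same arrays, so that SD is a spread over choices and not a sampling error. The named genes kept their direction in every alternative, with 94 losses of the threshold beside 1270 values that stayed the same. For comparisons of 2 groups the kept direction was largely fixed by the naming rule. It required groups that do not overlap, so leaving out or weighting arrays cannot reverse the sign. Leaving out an array of another group does not change the estimate at all. Of the list medians 985 values stayed the same, 35 moved, 11 gained and 9 lost the threshold. The labels give no pairing beyond shared replicate numbers. Of 18 same-numbered pairs of arrays 3 had deviations correlated above 0.1, all of them between Col-0 water deficit and tori 35-7 control (0.403, 0.258 and 0.177). Of the 6 differently numbered pairs of these 2 groups 2 also lay above 0.1, at 0.195 and 0.150, the first above 0.177, and the highest value of all was that of the 2 arrays that stood apart. Although 9 of 12 arrays correlated best with their own number, this is at most a weak hint from the data, not the design. With replicate number as a block the counts were 216, 211, 1, 98 and 160.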

Other observations

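The test of the agar, the tests without AT1G13609 and the tests of gene families were chosen after the values were seen, as was the fit without 2 arrays. Besides the 5 iron-deficiency genes in the plot of levels by array, 10 genes known to be induced by iron deficiency were listed before their values were seen. One of them, AT1G13609, proved to be among the 10 largest rises in Col-0. In Col-0 the others included PYE, a transcription factor of the iron response (0.96 ± 0.18, adjusted p = 0.0175), AT1G12030 (1.67 ± 0.31, adjusted p = 0.0167) and AT1G74770, a ubiquitin ligase gene (0.83 ± 0.17, adjusted p = 0.0323), which rose under water deficit with AT1G13609. The other 6 did not pass, with AT3G07720 at 0.45 ± 0.19, AT3G12900 at 0.41 ± 0.18 and CYP71B5 at -0.32 ± 0.13. In tori 35-7 none of the 10 passed singly, though 8 of the 10 were higher under water deficit, PYE by 0.41 ± 0.18. Between the genotypes under water deficit PYE was lower in tori 35-7 (-0.89 ± 0.18, adjusted p = 0.0349).

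The 5 iron-deficiency genes in the plot of levels by array rose in Col-0, and 5 of 5 passed without the 2 arrays that stood apart, so those arrays do not account for the rise. A wider iron-deficiency response in Col-0 is a hypothesis. The adjusted camera p-values of the 10 further genes cover only the tests of these genes and of the low-oxygen genes. These are fewer tests than for the fixed lists, so the adjusted p-values cannot be compared with those of the fixed lists. The median change of the 10 further genes was 0.43, with 9 of 10 above 0 (camera adjusted p = 5.59e-05, and adjusted p = 0.0139 with an estimated correlation). Without AT1G13609 it was 0.41 over 9 genes (camera adjusted p = 0.00147, and adjusted p = 0.0429 with an estimated correlation). Without the 2 arrays that stood apart the 10 genes kept the call (camera adjusted p = 3.93e-05) but lost it with an estimated correlation (adjusted p = 0.0549). A smaller response in tori 35-7 is a second hypothesis. Under water deficit the 10 genes were lower in tori 35-7 than in Col-0, with a median of -0.27 and 1 of 10 above 0 (camera adjusted p = 0.00542, and adjusted p = 0.0367 with an estimated correlation). That call was kept without each of the 12 arrays in turn and without AT1G13609 (camera adjusted p = 0.0165), but with an estimated correlation it was lost without AT1G13609 (adjusted p = 0.0923) and without the 2 arrays that stood apart (adjusted p = 0.106). On control medium the median was -0.00 (camera adjusted p = 0.63). The median interaction of the 10 genes was -0.22 (camera adjusted p = 0.0223), but it did not pass with an estimated correlation (adjusted p = 0.0585) or without AT1G13609 (camera adjusted p = 0.0624), and no single interaction passed. The call was also lost without Col-0 water deficit replicate 3 (0.0534), tori 35-7 control replicate 2 (0.114) or tori 35-7 water deficit replicate 1 (0.0714). Whether the response itself is smaller thus stays open. In tori 35-7 the median change of the 10 genes under water deficit was 0.28, with 8 of 10 above 0 (camera adjusted p = 0.0223, and adjusted p = 0.0585 with an estimated correlation). Without tori 35-7 control replicate 3 the unadjusted camera p was 0.0555. Without the 2 arrays that stood apart the adjusted p with an estimated correlation was 0.116. The media differ in agar, and iron supply from the agar cannot be told apart from water deficit, since both predict a rise in both genotypes.

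Gene families were also formed from symbols, as 37 families of at least 8 measured genes including the organelle-encoded ones, and tested in the 5 comparisons. Of 185 tests 2 passed. The 8 ATG autophagy genes had a median change of 0.27 under water deficit in tori 35-7 (camera adjusted p = 0.0265) and the 22 BGLU beta-glucosidase genes were 0.15 higher at the median in tori 35-7 than in Col-0 under water deficit (adjusted p = 0.0385). With an estimated correlation the adjusted p was 0.484 for both, and without the 2 arrays that stood apart it was 0.131 for both. All 8 ATG genes, most of them ATG8 genes, also belong to the fixed autophagy list, so their call repeats the same values and is no separate evidence.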
